A study of Mus musculus with 6 samples.

How the data were processed

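RNA from the lens of 6 mice was measured on Illumina BeadChips, arrays of beads that each carry copies of 1 probe. Per the labels, the mice were of the C57BL/6J strain and 18 weeks old. In 3 mice both copies of Fgf9 carried the Y162C change, a single amino acid substitution in fibroblast growth factor 9. The other 3 mice were wild type. Each array held RNA of 1 mouse, so the 3 samples of a group are separate animals. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on a column and turned into biotin-labelled cRNA with an Ambion MessageAmp kit. The labels give 1 female and 2 males in the wild type and 2 females and 1 male in the homozygotes.

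A pair of tables was used. Per the file headers, the first table holds the authors' deposited signal, a linear intensity per probe that is neither background-subtracted nor normalized between arrays, and beside it a detection p-value per probe and array. In the values, the detection p-value falls with the signal on each array in steps of 1 in 798, as a rank among negative control beads would. The second table holds the authors' processed intensity of the same arrays, on a linear scale, background-subtracted and normalized between arrays by a method that is not given in the sources used here. Its medians lie between 4.39 and 4.41, about 28% of its values are negative, and it ranks the probes of each array in the same order as the first table. GenomeStudio 2011.1 is named in the submitters' processing notes. Slide positions and scan times are not used here.

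The deposited signals were processed with limma 3.58.1 in R 4.3.3. Background was corrected by the normal-exponential method, with the mean and spread of the negative controls inferred from the detection p-values, and an offset of 16 was added. The arrays were quantile normalized on the linear scale, and log2 was taken. Quantile normalization gives all 6 arrays the same distribution, so a change that reached most transcripts in 1 direction would not be seen. The offset pulls the fold changes of dim probes toward 0.

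The array holds 25697 probes. Gene symbols came from the platform's probe annotation: 23978 probes have 1 symbol, 0 have several and 1719 have none. Symbols were checked through gene identifiers against the RefSeq genes of the assembly GRCm38.p6, which was used for names and for chromosome membership only. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were tested, which left 8618 probes and 6430 named genes. A gene with several tested probes is represented by the probe with the highest mean log2 value over the 6 arrays.

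Homozygous lenses were compared with wild-type lenses by limma's lmFit and eBayes with an intensity trend, with genotype as the only term. The test was two-sided, and p-values were adjusted by Benjamini-Hochberg over all tested probes. A gene counts as changed at an adjusted p under 0.05. A log2 fold change is the mean of the homozygous minus the mean of the wild-type log2 values. Where a probe was above background on 0 arrays of a group, the change is given as a bound ("at least"). The bound sets the brighter group's mean against the dim group's mean of, on each array, the higher of the probe's own value and the lowest value among detected probes. The number of arrays limits the precision of every value.

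The test, the named genes and the gene lists were fixed before the data were examined. The genes named are, per direction, up to 12 changed genes with the largest log2 fold change whose 3 homozygous values all lie on one side of the 3 wild-type values. Where a direction has fewer, it is filled with the genes of smallest unadjusted p that also do not overlap, reported as not passing. Fgf9 is named, and so are, in each list, up to 4 members that pass or else the 2 members of smallest p. Other genes were chosen after their values were seen. They are the members of a list beyond this rule, the added lists below and Slc6a6.

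Of 31 fixed gene lists, 28 had at least 5 tested members and were tested with limma's camera, a two-sided competitive test of whether a list shifts against the other genes. It used a preset correlation between genes of 0.01, and p-values were adjusted over the 28 lists. The correlation estimated per list and limma's fry were alternatives. With an estimated correlation camera also uses only the 4 residual degrees of freedom, which raises its p-values whatever the estimate. For crystallins, lens epithelium, ribosomal proteins and TGF-beta targets the estimates were -0.024, -0.074, -0.021 and -0.039, below the preset. The calls these lists lost in that setting therefore do not show that their genes vary together. For array weights and robust variance the same test was run with limma's cameraPR on the moderated t of those fits. Counts of members were also taken at p-values adjusted over the list alone. After the changed genes had been seen, 3 more lists were written, and they were tested only for the closing section.

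The procedure was tested on simulated data made from the 25697 probes of this comparison, in 10 rounds. Changes were placed only in probes that had passed the detection filter, 100 of each size per round, while 35 probes were called in the data. The procedure recovered 43.9% of these 2-fold changes and 77.5% of these 4-fold changes, and 5.8% of its calls were false. A shifted list was found in 10 of 10 rounds, and 1.5% of 200 random lists had p under 0.05. The simulated arrays shared the same background, and all members of the shifted list moved by the same amount. Arrays of unlike brightness and lists with small or uneven shifts are thus not covered. The simulated noise was independent between probes. These rates therefore do not cover lists whose genes vary together, such as the photoreceptor list with an estimated correlation of 0.899.

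The alternatives were no background correction, an offset of 50, the authors' processed values, median scaling in place of quantile normalization, other detection filters, sex as a covariate and the replicate number as a block. Median scaling divided the log2 values of each array by a factor that made the array medians equal. It did not scale the signal itself, and it moves the log2 values of bright probes by more than those of dim ones. Array weights, other variance models, the mean of a gene's probes, other thresholds and each array left out in turn were also tried. Sex as a covariate without wild type replicate 3 was added after the data had been seen. A block for the slide was not run. No difference between the sexes in the response to genotype was tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.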

Results

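Lens RNA of 3 wild-type mice and 3 mice homozygous for Fgf9 Y162C was profiled at 18 weeks of age, 1 array per mouse. Mean signal was 194, 200.4 and 191 on the wild-type arrays and 164.8, 165.7 and 161.6 on the homozygous arrays. The wild-type arrays detected 8713, 9671 and 9214 probes above background, and the homozygous arrays detected 7816, 8396 and 8141. Correlations across all tested probes, which are not independent replicates, lay between 0.981 and 0.985 within the homozygotes, between 0.957 and 0.978 within the wild type and between 0.949 and 0.979 across the groups. Wild type replicate 2 stood apart from the other 5 arrays on the first principal component, which held 43.2% of the variance. Wild type replicate 3 is labelled male, but Xist, the transcript of the inactive X chromosome, was above background on it and Y-linked Eif2s3y was not.

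The comparison asks how the lens transcriptome differs in mice whose FGF9 protein, a secreted growth factor, carries the Y162C change. The single Fgf9 probe was above background on 0 of the 6 arrays. Its signal was 74.8 to 87.7 and its detection p-value 0.406 to 0.769, so no fold change is given. The change is a substitution, so the probe does not check the genotype labels.

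In homozygous lenses 28 genes changed, 7 of them up and 21 down. The genes that rose included a water channel, a carbonic anhydrase and the oxygen-regulated subunit of hypoxia-inducible factor. Those that fell included transporters of glycine, glutamate and GABA, calcium-binding and synaptic proteins, and secreted matrix proteins. In all 28 genes the 3 homozygous values lay on one side of the 3 wild-type values. Such separation was seen in 15.1% of all tested genes and is given by chance in 10%.

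Igfl3, a member of the insulin growth factor-like family, rose 3.49-fold (log2 fold change 1.81, SE 0.17, n = 3 per group, limma adjusted p = 0.00102), and both of its tested probes passed. Aqp1, the water channel of the lens epithelium, rose 2.46-fold (log2 fold change 1.30, SE 0.16, limma adjusted p = 0.00343), and its 3 probes gave log2 fold changes of 1.11 to 1.30. Its normalized log2 signal was 9.70 ± 0.30 (SD, n = 3) in the wild type and 11 ± 0.22 (SD, n = 3) in the homozygotes. Car9, a membrane-bound carbonic anhydrase, was above background on 0 of 3 wild-type and 3 of 3 homozygous arrays and was at least 2.80-fold higher (limma adjusted p = 0.00367). Hif1a, which encodes that subunit of hypoxia-inducible factor, rose 2.19-fold (limma adjusted p = 0.0432) and was detected on 2 of 3 wild-type arrays. Ecrg4, a secreted peptide precursor, rose 2.09-fold (limma adjusted p = 0.00469). Pros1, the anticoagulant protein S, rose 1.97-fold, and Pgam2, a glycolytic phosphoglycerate mutase, rose 1.92-fold (limma adjusted p = 0.0395 and 0.0467). The next genes by p did not pass. Their log2 fold changes were 0.83 for Uaca, 1.02 for the tight junction gene Cldn10, 0.43 for the ribosomal gene Rpl23, 0.87 for Gstk1 and 0.96 for Gemin2, at limma adjusted p-values of 0.0711 to 0.101.

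Reln, the extracellular glycoprotein reelin, fell 7.18-fold (log2 fold change -2.84, SE 0.29, n = 3 per group, limma adjusted p = 0.00102). Calb2, the calcium-binding protein calretinin, fell 5.05-fold (log2 fold change -2.34, SE 0.23, limma adjusted p = 0.00102). Its second tested probe had a log2 fold change of -0.32 and did not pass. Minar2 fell 5.38-fold at the same adjusted p. Among transporters, the GABA transporter Slc6a13 was at least 4.61-fold lower and the vesicular glutamate transporter Slc17a6 at least 2.07-fold lower, since neither was above background on a homozygous array. The glial glutamate transporter Slc1a3 fell 3.94-fold and the glycine transporter Slc6a9 fell 3.14-fold. Gldc, the decarboxylase of the glycine cleavage system, fell 3.10-fold, with log2 signals of 8.20 ± 0.41 and 6.57 ± 0.46 (SD, n = 3) in the wild type and the homozygotes. These transporter and Gldc changes had limma adjusted p-values of 0.00244 to 0.0386. Gpx3, a secreted glutathione peroxidase, fell 5.99-fold and Crhbp, the binding protein of corticotropin-releasing hormone, fell 5.54-fold (limma adjusted p = 0.0395 for each). Prelp, a leucine-rich repeat protein of the extracellular matrix, fell 3.26-fold, and Cplx1, a regulator of synaptic vesicle release, fell 2.74-fold (limma adjusted p = 0.0467 and 0.0323). Of the 21 genes that fell, 5 were above background on 0 homozygous arrays, 11 on some and 5 on all 3, so many of these fold changes are set close to the detection limit. Their size depended on the background correction: the median log2 fold change of the 14 named genes that fell was -1.84, but -0.94 with no background correction and -1.27 with an offset of 50, and Reln stood at -1.44 and -1.98. The 7 that rose had a median of 1.13, and 0.74 and 0.90 in those settings.

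**Figure D1:**
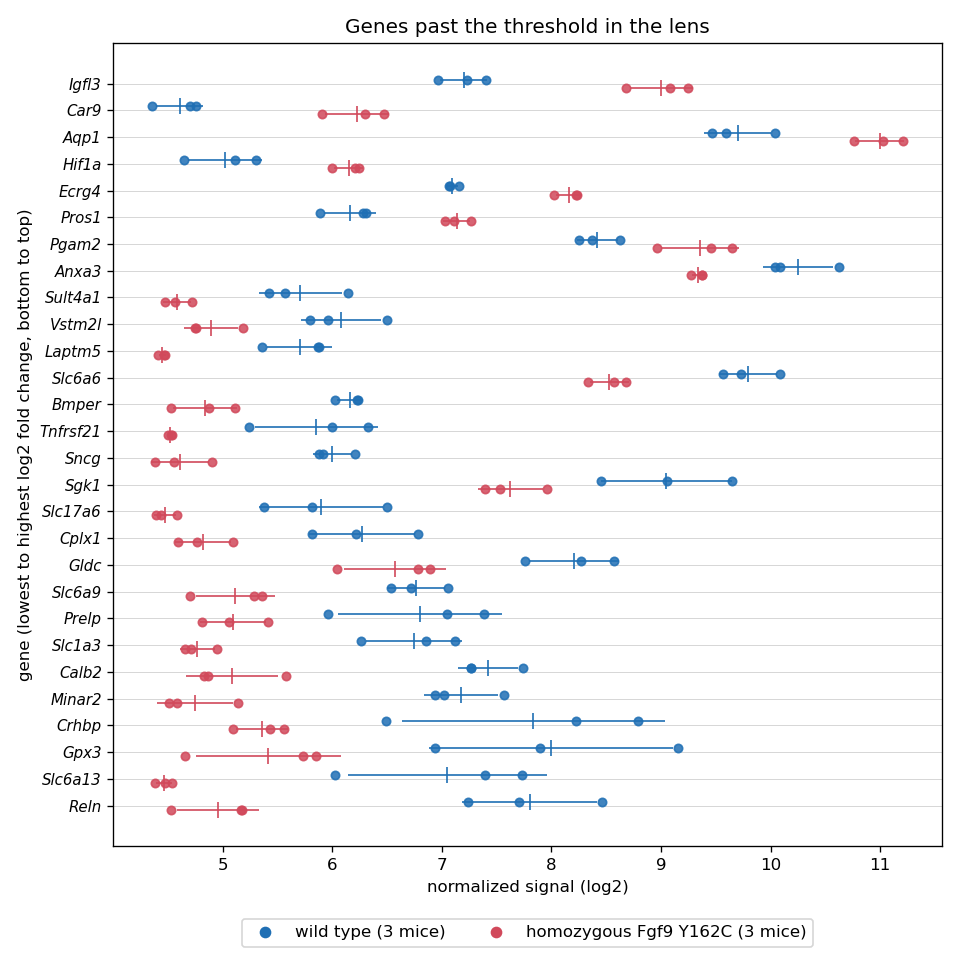
Normalized log2 signal (horizontal axis) of the 28 changed genes (vertical axis, ordered by log2 fold change) on each array. Points are single mice, vertical ticks are group means and horizontal lines are the SD over 3 mice; the 3 homozygous values lie on one side of the 3 wild-type values in all 28 genes.

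The number of changed genes depended on single arrays: it was 72 without wild type replicate 1, 32 without wild type replicate 2, 13 without wild type replicate 3, and 12, 9 and 9 without homozygous replicates 1, 2 and 3. With sex as a covariate it was 17, and 4 when wild type replicate 3 was also left out, a setting added after the data were seen. The covariate used the sex labels, which the sex genes of wild type replicate 3 go against, and a fit with that label changed was not run. The fit without this array also had fewer samples, so these counts do not measure a dependence on sex. Of the 21 named genes that passed, Calb2, Igfl3, Minar2, Reln, Slc1a3 and Slc6a9 passed without each of the 6 arrays in turn, and the other 15 lost the call or their detection at least once. Over all settings that tested them, the calls were lost in 11 of 19 for Hif1a (adjusted p up to 0.27, log2 fold change down to 0.42), 11 of 19 for Gpx3 (up to 0.42), 12 of 20 for Crhbp (up to 0.40), 12 of 19 for Prelp (up to 0.32), 13 of 20 for Pgam2 (up to 0.32) and 8 of 15 for Slc17a6 (up to 0.24). No background correction, sex as a covariate and no intensity trend each ended the call of all 6, and an offset of 50 that of all but Hif1a. With median scaling in place of quantile normalization the median of all tested genes moved to -0.3, and the split became 3 up and 168 down. Since this setting divides log2 values, the shift it imposes is not the same for dim and bright probes.

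Of the crystallins and the fibre membrane and cytoskeleton genes, 0 passed. Many are among the brightest probes, 12 of 15 and 6 of 19 within the top 100, where quantile normalization sets values by rank and small changes can be missed. Crystallins, the main soluble proteins of the fibre cells, had 15 tested members, of which 0 passed. Of the 15, 11 had a log2 fold change above 0 and 4 had one at or below 0. Their mean log2 fold change was 0.15, which turned to -0.02 with median scaling, where the median of all genes was -0.3, and was 0.32 with the authors' processed values (adjusted p = 1.5e-10). The list shifted upward against other genes (camera adjusted p = 0.016), but not with an estimated correlation (estimate -0.024, camera adjusted p = 0.26). Cryab had a log2 fold change of 0.37 and Crygf of 0.53, neither passing (limma adjusted p = 0.433 and 0.404). Gamma crystallin genes are near-identical and probes may bind more than 1 of them, so single members are uncertain. The crystallin shift also lost its call without wild type replicate 2 (adjusted p = 0.085), without homozygous replicate 3 (adjusted p = 0.055) and without the intensity trend (adjusted p = 0.075). Of 19 fibre membrane and cytoskeleton genes, 0 passed, and the list did not shift (mean 0.05, camera adjusted p = 0.45). The fibre cell nuclease Dnase2b had a log2 fold change of 0.54, and the receptor Epha2 of -0.54, neither passing.

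Lens epithelium markers had 10 tested members, of which Aqp1 rose and 9 did not pass. In this list, 9 members had a log2 fold change above 0, with a mean of 0.28 that turned to -0.08 with median scaling. It shifted upward (camera adjusted p = 0.0023), a call lost with an estimated correlation (estimate -0.074, adjusted p = 0.26) and with median scaling (adjusted p = 0.071). Lens transcription factors had 0 of 12 members passing and no shift (camera adjusted p = 0.28), with log2 fold changes of -0.47 for Meis1 and 0.34 for the Notch target Hey1.

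Markers of the inner retina and of glia lay lower in the homozygotes. Of 10 tested members Calb2, Sncg and Slc17a6 fell, and 6 members passed when adjusted over the list alone. Sncg, gamma-synuclein, fell 2.62-fold (limma adjusted p = 0.00757), and its second probe had a log2 fold change of -0.05. The mean log2 fold change was -1, and the list shifted downward (camera adjusted p = 5.8e-08), a call lost with an estimated correlation (adjusted p = 0.26). Its mean deviation from the 6-array mean was 0.15, 0.93 and 0.41 on the wild-type arrays and -0.59, -0.34 and -0.56 on the homozygous arrays. With Slc17a6, which was not above background in the homozygotes, at its bound, the mean was -0.96 and the median, -0.96, was unmoved. The mean was -0.41 with no background correction, -0.61 with an offset of 50 and -0.63 with no filter on dim probes, and the list passed in each.

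Photoreceptor markers followed a single array. Of 18 tested members 0 passed and 17 had a log2 fold change below 0, with a mean of -0.47. Without wild type replicate 2 the mean was 0.18 (camera adjusted p = 0.085). With all 6 arrays the list shifted downward (camera adjusted p = 0.0081), but not with an estimated correlation (adjusted p = 0.65), with median scaling (adjusted p = 0.65), with sex as a covariate (adjusted p = 0.13) or without homozygous replicate 1 (adjusted p = 0.19). The call was also lost with array weights (adjusted p = 0.2) and with robust variance (adjusted p = 0.078). With sex as a covariate but without wild type replicate 3, whose sex label is in doubt, it passed (mean -0.54, adjusted p = 0.0022). The mean was -0.26 with sex as a covariate, -0.25 without homozygous replicate 1 and -0.22 with array weights, and without wild type replicate 1 it was -0.88. With 1 member at its bound the median was -0.49, against -0.51 as fitted. Guca1a had a log2 fold change of -1.14 and Rcvrn, not above background on a homozygous array, was at least 1.21-fold lower, neither passing. The list's mean deviation was 1.46 on wild type replicate 2, against -0.56 and -0.19 on the other wild-type arrays and -0.68, 0.15 and -0.18 on the homozygous arrays. Markers of the pigment epithelium and pigment cells also lay highest on that array, at 1.19, against 0.04 on both other wild-type arrays and -0.58, -0.05 and -0.65 on the homozygous arrays. Of 9 tested members 0 passed over all genes and 4 passed when adjusted over the list alone, with a mean of -0.85 (camera adjusted p = 0.00064). That call was lost with an estimated correlation (adjusted p = 0.38) and with median scaling (adjusted p = 0.13). Without wild type replicate 2 the mean was -0.46 (adjusted p = 0.028). It was -0.42 with no background correction, -0.56 with an offset of 50 and -0.58 with no filter, passing in each. With 2 members at their bound the median was -0.45, against -0.81 as fitted. Of the melanin synthesis genes, Dct had a log2 fold change of -1.26, and Tyrp1, above background on 0 homozygous arrays, was at least 1.37-fold lower.

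**Figure D2:**
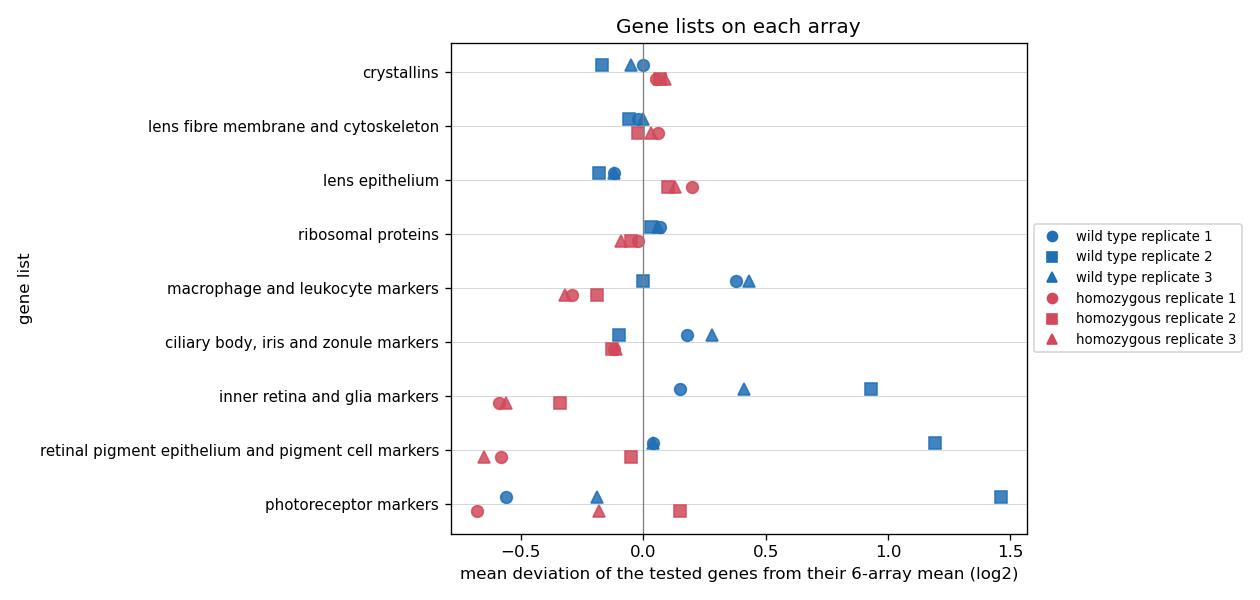
Mean deviation of each list's tested genes from their 6-array mean (horizontal axis, log2) on each array, for 9 lists (vertical axis). Each symbol is 1 mouse; the photoreceptor list lies at 1.46 on wild type replicate 2, and the inner retina and glia list is above 0 on the 3 wild-type arrays and below 0 on the 3 homozygous arrays.

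Macrophage and leukocyte markers had 8 tested members, 7 with a log2 fold change below 0, and a mean of -0.54. Since 4 of the 8 were above background on 0 homozygous arrays, the mean with these at their bound was -0.39 and the median -0.30, against a fitted median of -0.42. The mean was -0.19 with no background correction, -0.28 with an offset of 50 and -0.27 with no filter, and the list passed in each. Laptm5, a lysosomal membrane protein of blood cells, was at least 1.81-fold lower (limma adjusted p = 0.0113). Lyz1, Laptm5, Fcer1g and C1qb passed when adjusted over the list alone. The list shifted downward (camera adjusted p = 5.2e-05), a call lost with an estimated correlation (adjusted p = 0.38). Ribosomal protein genes had a mean of -0.1 over 22 members, 0 of them passing, and of -0.42 with median scaling, where the median of all genes was -0.3. The list shifted downward (camera adjusted p = 0.012), but not with an estimated correlation (estimate -0.021, camera adjusted p = 0.26). That call was also lost with the authors' processed values, without the intensity trend, without wild type replicate 1 and without homozygous replicate 3 (adjusted p = 0.19, 0.075, 0.065 and 0.083). Ribosomal probes may also bind near-identical copies. Rpl27 and Rps19 had log2 fold changes of -0.31 and -0.25. Targets of TGF-beta and of epithelial-mesenchymal transition had a mean of 0.22 over 8 members, 0 passing, 0.09 with no background correction and -0.03 with median scaling. Their upward shift (camera adjusted p = 0.049) was lost in 16 of 21 other settings, with adjusted p-values up to 0.36, the value with an estimated correlation. Mmp2 and Timp1 had log2 fold changes of 0.56 and 0.46.

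No shift passed for the lists closest to FGF signalling. FGF ligands and receptors had 7 tested members of 25 listed, 0 passing (camera adjusted p = 0.56). Of the 25, 24 were on the array, and those not tested did not pass the detection filter. The members of smallest p, Fgf13 and Fgf12, are listed by family name and are not receptors. Fgf13 was above background on 3 of 3 homozygous and 0 of 3 wild-type arrays (limma adjusted p = 0.389), and Fgf12 had a log2 fold change of -0.51. Of the receptor genes, Fgfr3 had a log2 fold change of 0.95 (limma adjusted p = 0.507), Fgfr2 of 0.16, Fgfr1 of -0.002 and Fgfrl1 of -0.10. FGF and ERK feedback genes had 11 tested members of 25 listed, 24 of them on the array, so the absence of a shift covers only part of these genes. Of the 11, 0 passed, with a mean of -0.18 (camera adjusted p = 0.19), and Spred1 and Ier3 had log2 fold changes of -0.51 and -0.82. Heparan sulphate proteoglycans and their enzymes had 0 of 14 passing (camera adjusted p = 0.62). Agrn, the proteoglycan agrin, had a log2 fold change of -0.75 and passed when adjusted over the list alone (limma adjusted p = 0.018, and 0.152 over all probes), while Sulf1 was at 0.35, or -0.03 with median scaling. Other growth factor receptors and ligands had 0 of 19 passing (camera adjusted p = 0.58). Igfbp7 and Igf2 had log2 fold changes of 0.60 and -0.75, and both passed when adjusted over the list alone.

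Lens capsule and basement membrane genes had 0 of 15 passing (camera adjusted p = 0.41), but 4 passed when adjusted over the list alone: Col4a1 and Sparc at 0.38 and 0.36, and Col18a1 and Agrn at -1.96 and -0.75. Ciliary body, iris and zonule markers had 0 of 8 passing (camera adjusted p = 0.56), with 2 passing when adjusted over the list alone, Mfap4 at -1.32 and Wfdc1, above background on 0 homozygous arrays, at least 2.02-fold lower. Antioxidant and glutathione genes had 1 of 25 passing, Gpx3 (camera adjusted p = 0.85), and Aldh3a1, an abundant aldehyde dehydrogenase, had a log2 fold change of -0.52 and passed over the list alone. The unfolded protein response list had 0 of 14 passing (camera adjusted p = 0.42), with Asns at -1.11, passing over the list alone, and Ppp1r15a at -0.37. Glycolysis and sorbitol pathway genes had 0 of 14 passing (camera adjusted p = 0.094), with Pfkl at 0.68, passing over the list alone, and Aldoc at 0.23, or -0.11 with median scaling. The glycolysis list passed with sex as a covariate (mean 0.14, adjusted p = 0.041) and without wild type replicate 2 (mean 0.17, adjusted p = 0.0026). Organelle removal and autophagy genes had 0 of 15 passing (camera adjusted p = 0.19), with Dnase2b passing over the list alone and Lamp1 at 0.23, or -0.16 with median scaling. Interferon response genes had 0 of 8 passing (camera adjusted p = 0.58), with Usp18 at 0.71, passing over the list alone, and Ifit3 at -0.64.

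In the remaining lists 0 members passed, over all genes or over the list alone, with the exceptions given here. The cell cycle list (11 tested) had a camera adjusted p of 0.28, with Mcm4 at -0.31 and Birc5 at 0.26. Cholesterol synthesis (14 tested) was at 0.83, with Sqle at -0.33 and Hsd17b7 at 0.29, or -0.13 with median scaling. Heat shock proteins (9 tested) were at 0.19, with Hspb8 at 0.38 and Hspb1 at 0.32, or -0.05 with median scaling. Oxidative phosphorylation (31 tested) was at 0.66, with Cox5b at -0.26 and Ndufa1 at 0.32, or -0.03 with median scaling. Immediate early genes (6 tested) were at 0.28, with Egr1 at 0.36 and Dusp1 at 0.27, or -0.14 with median scaling. Circadian clock genes (10 tested) were at 0.37, with Ciart at 0.43 and Nr1d1 at 0.35, or -0.04 with median scaling. Genes neighbouring Fgf9 on chromosome 14 (9 tested) were at 0.4, with Cab39l at -0.69 and Ift88 at 0.27. The cornea, blood and endothelium, and sex-linked lists had 3 tested members each, too few for the list test. Over the list alone Aldh3a1 passed in the cornea list, where Krt4 was at 0.35. The haemoglobin gene Hba-a1, at -2.29, passed over the list alone in the blood list, where Egfl7 was at 0.25, or -0.15 with median scaling. Among sex-linked genes Eif2s3x was at -0.18 and Kdm6a at 0.16, or -0.21 with median scaling, neither beyond the spread between mice.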

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

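The 2 tests in this part were chosen after the result was seen. Xist gave a normalized log2 value of 6.18 on wild type replicate 3, which is labelled male, against at most 4.50 on the other male-labelled arrays over both Xist probes and 5.22, 5.60 and 6.08 on the female-labelled arrays with the same probe. It drew attention because it goes against the sex label, which the genotype comparison does not use. A swap with another of the 6 mice would leave a partner out of place, and 0 of the other 5 arrays had Xist or Eif2s3y against its label. A smaller amount of female RNA mixed into mostly male RNA would leave Eif2s3y above background, but its log2 value there was 4.25, against 5.48 on the lowest other male-labelled array. The Zfy2 probe was above background on this array (5.16), but also on the female-labelled homozygous replicate 2 (4.86) and not on the other 2 male-labelled arrays, so it does not follow sex here. A Zfy1 probe, also Y-linked, was above background on this array (4.76, detection p-value 0.0464) and on homozygous replicate 3 (5.02), which is labelled male. It was above background on 0 of the female-labelled arrays, but also not on wild type replicate 2 (4.57), which is labelled male. The second Zfy1 probe was not above background on any array. Some male RNA is thus neither shown nor excluded. A single wrong sex label, a mix that is mostly female, or an exchange with a mouse outside the 6 may account for it and stays open, and no biological explanation was tested.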

How the results depend on the processing

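All alternatives were planned, except sex as a covariate without wild type replicate 3, which was chosen after seeing the data. In each setting with its own fit, every one of the 28 changed genes that was tested kept its direction, and Igfl3, Reln, Calb2 and Minar2 passed wherever they were tested. The count of changed genes was 17 with no background correction, 18 with an offset of 50, 171 with median scaling, 6 among probes detected on all 6 arrays, where only 10 of the 28 genes were tested, and 17 with sex as a covariate. It was 60 with array weights, 16 without the intensity trend, 18 with the mean of a gene's probes, 43 at an adjusted p under 0.1 and 137 at an unadjusted p under 0.01 with a fold of at least 1.5. Sex as a covariate without wild type replicate 3 gave 4. It was 32 with the authors' processed values, 27 of them shared. Leaving out 1 array gave 9 to 72 genes and 5 to 7 shifted lists, with fewer samples, and 8 to 23 genes shared with the 28. Shifted lists numbered 8, and 4 among probes detected on all 6 arrays, 5 without the intensity trend, 7 with array weights, 6 with robust variance, 0 with an estimated correlation and 2 with fry, which does not compare a list with other genes: lens epithelium, 1 of the 8, and immediate early genes, which is not. Besides that list, calls were gained by cell cycle and oxidative phosphorylation with median scaling, glycolysis with sex as a covariate and without wild type replicate 2, and lens capsule with sex as a covariate without wild type replicate 3. Except for fewer samples or genes tested, the cause was not tested.

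With the replicate number as a block 102 genes passed. Same-numbered arrays of the groups had correlations of 0.20, 0.19 and -0.03 in their deviations. Differently numbered arrays had correlations from -0.21 to 0.04. Not every array correlated best with its own number, so a pairing of the mice by number is neither shown nor excluded.

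Median scaling, a division of the log2 values, moves the median of all genes to -0.3, and bright probes by more than dim ones. It turned the log2 fold changes of genes that did not pass: Hey1 to -0.06, Sulf1 to -0.03, Hsd17b7 to -0.13, Hspb1 to -0.05, Lamp1 to -0.16, Aldoc to -0.11, Ndufa1 to -0.03, Dusp1 to -0.14, Nr1d1 to -0.04, Egfl7 to -0.15 and Kdm6a to -0.21. Leaving out 1 array gave -0.03 (without homozygous replicate 1) to 0.26 for Kdm6a, -0.37 to 0.02 (without wild type replicate 3, also with sex as a covariate) for Eif2s3x, and -0.88 to 0.18 (without wild type replicate 2) for the mean of the photoreceptor list. Lists that did not pass in the main fit changed the direction of the test in 24 of their 435 values in other settings, and did not pass where they did so. Fgf9, below background on all 6 arrays, was tested only with no filter (log2 fold change -0.08, adjusted p = 0.86), and a slide block was not run. Signal over background limits the fallen genes, since 16 of the 21 were undetected on at least 1 homozygous array.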

Other observations

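Tests chosen after the result was seen are those of photoreceptors, array brightness, the share of lens epithelium and solute carriers. The tests of ciliary epithelium, neurons, hypoxia-inducible factor targets, chromosome 14 and other splits were written before their results. The 3 added lists were written after the changed genes were known, and 4 hypoxia-inducible factor targets had been seen in the glycolysis list. The ciliary and hypoxia medians lay within the bounds set in advance against these explanations, but not by more than the spread of the members. That further requirement was applied after the medians were seen, and both are treated as undecided.

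Solute carriers made up 5 of the 21 genes that fell, against 1.82% of the tested genes. They were Slc6a13, Slc6a9, Slc1a3, Slc17a6, whose call was lost in 8 of 15 other settings, and the taurine transporter Slc6a6, which fell 2.40-fold (limma adjusted p = 0.00307) and was chosen after its values were seen. Since the family was noticed in the changed genes, all 66 symbol stems with at least 10 tested genes were compared. Solute carriers had a p of 3e-05, and an adjusted p of 0.0019 (two-sided Fisher's exact test), and the next stem had 1. This test treats genes as independent, but all were measured on the same mice and may vary together. It therefore cannot decide on a chance share of the family, and no function of the transporters was tested. At an unadjusted p under 0.05, 11 of the 117 tested solute carrier genes had lower and 4 had higher values, against 332 and 256 of all 6430 tested genes.

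The wild-type arrays were not alike in the genes that fell. Wild type replicate 2, with the highest photoreceptor and pigment markers, had the lowest wild-type value in 10 of the 21 genes, among them Crhbp, Gpx3, Prelp, Reln and Slc6a13. It had the highest in 8, among them Calb2, Slc17a6, Slc1a3, Sncg and Cplx1.

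Tissue carried along with the wild-type lenses is a candidate explanation for the fallen genes, among them Calb2, Sncg and Slc17a6. Pigment epithelium markers lay lower as a list, but 0 of the 9 tested members passed over all genes. Without wild type replicate 2, 16 tested members of the photoreceptor list had a median log2 fold change of 0.18 (interquartile range 0.27). The 16 fallen genes tested in that fit had -1.73, but they were chosen for their fall. The list median above 0 argues against more retina with photoreceptors in wild type replicates 1 and 3 than in the homozygotes. Over all 6 arrays the list median was -0.51. Sag stood at 8.88 in the wild type and 7.91 in the homozygotes, and Gnat1 at 11.52 and 11.20. Both were above background on all arrays of both groups, so photoreceptor RNA was not limited to wild type replicate 2. A larger amount of retina on that array stays open. Dimmer homozygous arrays were examined with median scaling, which divides log2 values and is not a scaling of the signal itself. The 6212 tested probes within the brightness range of the fallen genes had a median of -0.34 and a lower quartile of -0.50. The least fallen gene stood at -1.29. Since the fallen genes were chosen for their fall, they had to lie below most other probes, so the comparison cannot decide on this cause. General neuron genes had a median of -0.71 (7 of 8 tested members below 0, camera p = 1.3e-05, p = 0.077 with an estimated correlation) and of -0.41 without wild type replicate 2 (camera p = 0.00015), with Syp at 7.25 against 6.13 and Uchl1 at 9.19 against 9.31, in line with neurons or their RNA in the wild-type samples. Ciliary epithelium and vitreous genes had a median of -0.23 (5 of 5 below 0, camera p = 0.058, p = 0.14 with an estimated correlation), so this source stays open, as does an effect of the genotype on cells of the lens.

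Of the 28 changed genes 1, Sncg, lies on chromosome 14, which holds 3.13% of the tested genes (one-sided Fisher's exact p = 0.59). A segment of another strain around Fgf9 that acts only on genes of this chromosome would thus not account for most of the changes. Whether such a segment acts on Sncg, or on genes elsewhere, cannot be told from this count. Only 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, called as many as 28 genes, and the highest other split called 0. With 10 splits a share under 0.05 is out of reach.

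A larger share of epithelium in the RNA was a hypothesis for the rise of Aqp1. The other 9 tested epithelium markers had a median log2 fold change of 0.18 (interquartile range 0.21, 8 of 9 above 0), below the 1.11 of the smallest Aqp1 probe. Aqp1 was the only member to pass, so a lower median of the others was likely from the outset. The highest of them was 0.39, so a share that raised all markers alike would not reach the Aqp1 rise. A larger share as part of the cause stays open. Since Car9 is a known target of hypoxia-inducible factor and Hif1a, whose call was lost in 11 of 19 settings, rose too, a higher activity of the factor was tested on 16 other targets. Their median was 0.08 (camera p = 0.11, p = 0.16 with an estimated correlation), and without wild type replicate 2 it was 0.19 (camera p = 0.0054). Of the 16 targets 11 lay above 0 and 5 below, from 0.53 for Fam162a to -0.75 for Vldlr, and the hypothesis stays undecided.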
